A study of Homo sapiens with 19 samples.

How the data were processed

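Small RNA was sequenced from Caco-2 cells, an established human colorectal epithelial line, and from the medium of those cells. Per the labels, the series holds 19 libraries in 5 groups: cell lysate (3 libraries), total extracellular RNA (exRNA, 4), the pellet of a 40000 xg spin (P40, 4), the pellet of the following 100000 xg spin (P100, 4) and the supernatant left after that spin (S100, 4). RNA of total exRNA and S100 was precipitated before Trizol, while RNA of P40, P100 and the cells was taken up in Trizol directly. Comparisons of total exRNA or S100 with P40, P100 or lysate therefore differ in RNA preparation as well as in fraction. The effects of these cannot be told apart there. Libraries were made with the RealSeq-AC kit and read as single ends of 50 bases. A batch number is given for each sample and equals its replicate number, so the numbers pair samples by label. No label says that replicates came from separate cultures, so p-values measure only the spread between these samples.

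The deposited files hold raw counts per mature human miRNA, 1 file per library, listing only miRNAs with at least 1 count. Per the submitters' processing notes, cutadapt 1.16, FastQC and Bowtie2 were used with GRCh38. The order of steps, the alignment parameters, the filter applied before counting, the handling of reads that match several miRNAs and the miRNA annotation release were not given in the sources used here. Near-identical mature sequences (miR-17-5p and miR-106a-5p, miR-301a-3p and miR-301b-3p, miR-103a-3p and miR-107, the let-7, miR-320 and miR-378 families, miR-663a and miR-663b, miR-10396a and miR-10396b) may therefore have exchanged reads, and values of single members are uncertain in that respect. No molecular identifiers were used, so intervals and floors below cover counting error only.

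A miRNA missing from a file was taken as 0 counts. Across libraries 1043 miRNAs were listed. Libraries with fewer than 100 detected miRNAs were left out, which removed S100 replicate 1 (48 counts, 28 miRNAs) and left 18 libraries with 10017 to 225290 counts (median 35940). A floor of 3 counts corresponds to 13.3 to 299 CPM (counts scaled to a common library size) across these libraries. Where a group had 0 counts of a miRNA, the ratio is given as at least the value that 3 counts over that group would produce. With 1 to 3 counts the ratio is given with its exact 95% counting interval.

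Counts were analysed in R 4.3.3 with edgeR 4.0.16. miRNAs were kept by filterByExpr on the groups (minimum count 10, minimum total 15), which left 227 miRNAs holding 98.5% to 99.1% of the counts of each library. Library sizes were scaled by the trimmed mean of M values (TMM), and 1 robust quasi-likelihood model was fitted to the 5 groups (common biological coefficient of variation 0.419). Each of 10 pairwise comparisons was tested by the quasi-likelihood F test, and p was adjusted over the 227 miRNAs by Benjamini-Hochberg. A miRNA is called higher or lower at an adjusted p below 0.05, with no minimum fold. Scaling used the counts alone, so higher and lower refer to the scaled share of a miRNA in a library. They do not give its amount in a fraction. CPM are TMM-scaled means with SD, log2 fold changes carry an SE derived from F, and log2 CPM used a prior count of 2. Groups were called non-overlapping when every library of one lay above every library of the other, which chance gives for 5.71% of miRNAs with 3 and 4 libraries, 10.0% with 3 and 3, and 2.86% with 4 and 4. These shares hold for miRNAs not chosen by a test. Called miRNAs were chosen for a large difference, so their counts of non-overlap and of equal sign describe them and add no support.

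13 miRNA lists were fixed before the data were examined: intestinal epithelial, let-7 and miR-98, miR-17~92 and paralog clusters, the miR-10, miR-99, miR-100 and miR-125 family, colorectal tumour associated, extracellular vesicle associated, blood cells, neural, liver, mesenchymal, muscle, the placenta cluster, and miRBase entries overlapping other RNA classes (rRNA, tRNA, snoRNA and similar). Lists with at least 3 tested members were tested by camera (limma 3.58.1, preset correlation 0.01) and again with the correlation estimated from the data, each adjusted by Benjamini-Hochberg over the lists of a comparison. A list is said to pass at an adjusted p below 0.05 with the preset correlation. For the entries overlapping other RNA classes the estimated correlation was 0.364. With estimated correlations no list passed in any comparison (lowest camera adjusted p = 0.210, P40 against lysate). Calls of members were also adjusted over the list alone. The groups, comparisons, filter, test and alternatives were likewise set before the data were examined.

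miRNAs named in the report follow a rule. They are the 8 largest rises and 8 largest falls of a comparison (5 and 5 against total exRNA) among called, non-overlapping miRNAs with a mean of at least 100 CPM in the higher group, the 4 most abundant tested members of each list, and the 5 most abundant miRNAs of each group. Any other miRNA named is marked as chosen after its values were seen. Positions are GRCh38 and come from GENCODE and RefSeq gene tables. A hairpin gene was found for 224 of the tested miRNAs and a hairpin sequence for 216. A hairpin was linked to another RNA class when it lay on such a gene or shared a run of 18 bases with such a transcript. The list of entries overlapping other RNA classes was fixed without this check, and its name serves as a label. The check linked 5 of its 16 tested members and found no link for 11.

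Detected miRNAs, the share of the 10 most abundant miRNAs and total counts were compared by exact permutation. Detection was counted after thinning each library to 10017 counts (mean of 100 draws). Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for these steps.

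The test was checked on simulated data with the libraries and depths of each comparison, 227 miRNAs and 40 changed miRNAs (10 draws). For S100 against P100, 21% of changes of 2-fold, 69% of 4-fold, 94% of 8-fold and 99% of 16-fold were recovered, with a mean of 1.1 false calls. Across the 10 comparisons recovery was 11% to 24% at 2-fold, 63% to 78% at 4-fold, 85% to 97% at 8-fold and 95% to 100% at 16-fold, with 0.3 to 1.4 false calls. The simulated changes went up as often as down, and the other miRNAs were equal between the 2 groups. The real comparisons of S100 called 120 to 144 of 227 miRNAs. Recovery and false calls were not measured for changes in so many miRNAs. The value of the batch numbers as pairs was checked once: deviations from group means of libraries with the same number in different groups had a mean correlation of -0.0301 (from -0.568 to 0.311, 7 of 32 pairs above 0.1), against 0.00986 for other libraries. Samples were therefore not paired.

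Alternatives set beforehand were DESeq2 size factors in edgeR, library size only, no filter on low counts, a 2-fold minimum, the replicate number as a block, all libraries kept, a fit of only the 2 groups compared, DESeq2 1.42.0 and leaving out each library in turn. For the permutation measures they were detection at 3 counts, a lower depth (1001 counts), the single most abundant miRNA and the short library. Each fit without a library was filtered and scaled anew. The filter asks for its minimum count in as many libraries as the smallest group holds, and that group shrank without a lysate or S100 library. Shifts in those fits therefore mix filter and scaling with the effect of the library itself. 3 alternatives were added after the data were seen. They were thinning to equal depth, removal of miR-7704 and the entries overlapping other RNA classes, and leaving out 3 libraries. These (P40 replicates 3 and 4, total exRNA replicate 2) lay together on 1 axis and are called set apart. P40 replicates 1 and 2 lay as far out on its other side and were not left out as a pair.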

Results

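Mature miRNAs were counted in Caco-2 cells and in their culture medium, after cells near confluence had spent 24 h without serum and antibiotics. The medium was taken as total exRNA or was split by ultracentrifugation into P40, P100 and S100. Depth differed between groups: S100 libraries held 198878 to 225290 counts (n = 3), cell lysate 37453 to 157051 (n = 3), total exRNA 34427 to 61622 (n = 4), P40 10490 to 26096 (n = 4) and P100 10017 to 27027 (n = 4). The fourth S100 library, replicate 1, held 48 counts and was left out.

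miR-92a-3p, a growth-promoting miRNA of the miR-17~92 family made from hairpins in MIR17HG and MIR106AHG, was the most abundant miRNA of 4 groups. It made up 28.9% ± 4.44 of counts in cell lysate (SD, n = 3), 24.1% ± 1.92 in P100 (n = 4), 19.9% ± 4.72 in P40 (n = 4) and 12.2% ± 2.08 in total exRNA (n = 4). In S100 the most abundant miRNA was miR-22-3p (11.2% ± 1.89, n = 3), which lies in MIR22HG at chr17:1713903-1713987 and is widely expressed in differentiated tissue. It was followed by miR-320a-3p (9.04%; chr8:22244966-22245037), miR-92a-3p (8.17%), miR-423-5p (5.90%; NSRP1, chr17:30117079-30117172) and miR-378a-3p (5.35%; intron of PPARGC1B, chr5:149732825-149732890). miR-7704 (chr2:176188843-176188901, annotated in HAGLR and HOXD1) came second in P100 (14.9% ± 2.79), P40 (7.50% ± 3.80) and total exRNA (9.31% ± 4.92). miR-373-3p and miR-372-3p, embryonic stem cell miRNAs of a cluster at chr19:53787675-53788773, were among the 5 most abundant of all extracellular groups but S100, and miR-373-3p held 5.12% of counts in lysate. Further leading miRNAs were miR-103a-3p (5.46%), miR-200c-3p (4.13%) and miR-93-5p (3.67%) in lysate, and miR-21-5p in total exRNA (5.99%) and P40 (2.86%).

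S100 differed most from the other groups. Its libraries had a mean Spearman correlation of 0.973 with each other and of 0.502 to 0.582 with other groups, whereas P40 and P100 reached 0.813 with each other, P40 and total exRNA 0.795, and lysate and P40 0.713. Replicates of a group correlated at a mean of 0.889 and pairs from different groups at 0.671. The first principal component (34.0% of variance) set S100 apart from all other libraries, and the second (22.2%) placed cell lysate and P100 at opposite ends.

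**Figure D1:**
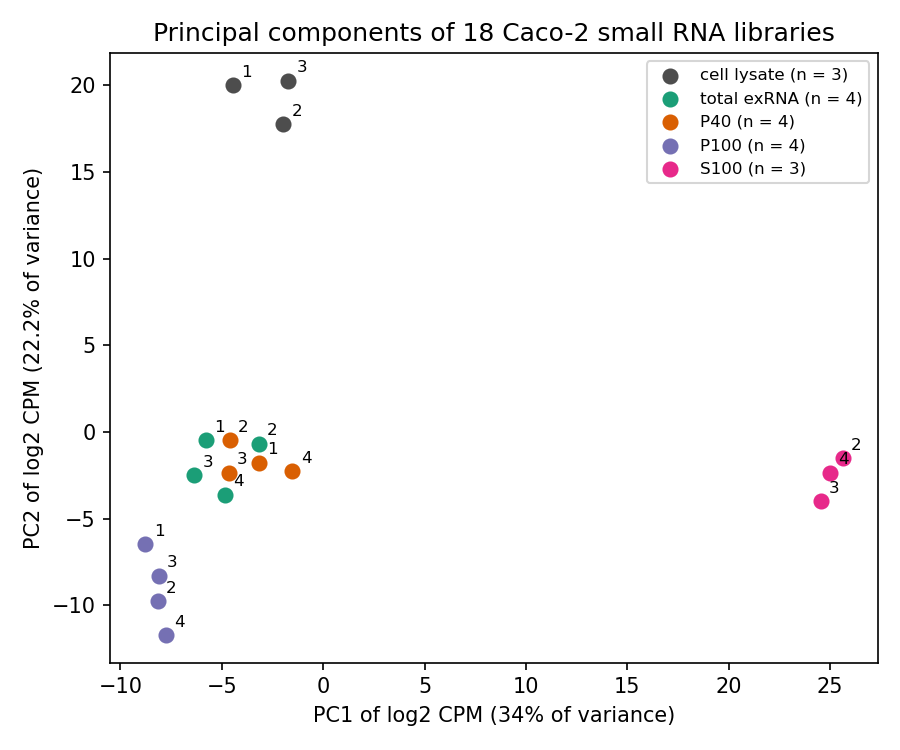
Principal components of log2 CPM of the 227 tested miRNAs. Each point is a library, coloured by group.

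Total exRNA against cell lysate asks which miRNAs of the cells were over- or underrepresented in the medium before fractionation. miR-21-5p (in VMP1, chr17:59841266-59841337), which is raised in most carcinomas, was higher in total exRNA by a log2 fold change of 1.50 ± 0.35 (SE; 55845 ± 14186 CPM, SD, n = 4, against 19727 ± 8035, n = 3). miR-194-3p (-4.12 ± 0.42), from a hairpin enriched in gut epithelium, and miR-25-5p (-2.71 ± 0.48) were lower. The abundant miR-92a-3p (-1.58 ± 0.27), miR-378a-3p (-1.48 ± 0.25) and miR-483-5p (-1.81 ± 0.28), the last from the IGF2 locus, were also lower, as was let-7a-5p (-1.97 ± 0.40) of the growth-restraining let-7 family. miR-5100 and miR-619-5p had no count in lysate and were at least 156-fold and at least 37.6-fold higher. miR-10395-3p had a ratio of 0.0133 (exact 95% counting interval 0.00272 to 0.0393).

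In this comparison 43 miRNAs were higher and 37 lower in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these 80, 70 did not overlap between groups and 77 had the same sign in each of the 3 batch numbers. The number lower was 23 without lysate replicate 2 and 24 without total exRNA replicate 4. With library size only the split was 47 higher and 19 lower and the median of all miRNAs moved by 0.30, without the low-count filter 46 and 21, and at equal depth 23 higher. The list of miRBase entries overlapping other RNA classes (16 of 59 tested) was shifted upward with 11 members higher and 0 lower (camera adjusted p = 0.000416, adjusted p = 0.428 with an estimated correlation). Total exRNA replicate 2, set apart from its group, went against this with 1.99% of counts in the list, below the lysate mean of 2.73%, while the other 3 libraries had 7.78% to 12.4%. No other list passed, although without lysate replicate 1 there were 2. Extracellular vesicle associated miRNAs had 4 higher and 2 lower (5 and 2 adjusted over the list alone), intestinal epithelial miRNAs 2 and 5, and let-7 miRNAs 0 and 2 (0 and 4 adjusted over the list alone). The colorectal tumour list had 2 higher and 0 lower, with a median of -0.05, a mean of 0.05 and an upward test.

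P40 against cell lysate asks what the pellet of the lower-speed spin, which collects larger vesicles and particles, held relative to the cells. miR-10396b-5p (chr21:8436324-8436374, within the 45S rRNA gene RNA45SN1) was higher by 5.66 ± 0.50 (3804 ± 711 CPM, n = 4, against 87.1 ± 47.4, n = 3). miR-1246, which shares sequence with U2 snRNA pseudogenes (chr2:176600980-176601052), was higher by 4.29 ± 0.47, and by 4.91 without lysate replicate 1. miR-451a, an erythrocyte miRNA, was at least 66.7-fold higher, with 0 counts in 260500 lysate counts and 71 in 70031 P40 counts. miR-4466 was at least 30.6-fold higher. miR-200c-3p (in MIR200CHG, chr12:6963699-6963766; -1.17 ± 0.24), which holds cells in the epithelial state, miR-103a-3p (-1.99 ± 0.34; PANK2 and PANK3), miR-194-3p (-2.50 ± 0.40) and miR-200b-5p (-2.61 ± 0.75) were lower.

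Here 31 miRNAs were higher and 30 lower, with 52 of the 61 not overlapping and 58 having the same sign in all 3 batch numbers. The split became 47 and 19 with library size only (the median of all miRNAs moved by 0.35), 16 and 11 in a fit of only these groups, 18 and 14 at equal depth, and 37 and 17 without the 3 libraries set apart. Among entries overlapping other RNA classes 9 were higher and 2 lower (camera adjusted p = 0.00688, adjusted p = 0.327 with an estimated correlation). This was the only list of 9 tested to pass, with 4 passing when the replicate number was a block, 5 without lysate replicate 1, and 2 without P40 replicate 1, 2 or 3. Its share of counts was 6.11% and 5.97% in P40 replicates 1 and 2. In P40 replicates 3 and 4 it was 3.83% and 3.16%, below lysate replicate 1 (4.09%) but above the other lysate libraries (2.30% and 1.79%). Vesicle associated miRNAs had 5 higher and 0 lower (6 and 1 adjusted over the list alone, camera adjusted p = 0.0589), but their share exceeded the lysate mean of 5.42% only in P40 replicates 3 and 4 (9.66% and 10.3%, against 4.80% and 4.93% in replicates 1 and 2). Intestinal epithelial miRNAs had 0 and 6 (1 and 6 adjusted over the list alone, camera adjusted p = 0.0717). The colorectal tumour list (14 of 17 tested) had a median of 0.05, a mean of -0.02 and a downward test.

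P100 against cell lysate asks the same of the high-speed pellet, in which small vesicles and large complexes collect. miR-7704 was higher by 2.24 ± 0.51 (157709 ± 39994 CPM, n = 4, against 33316 ± 21697, n = 3), and by 3.06 without lysate replicate 1. miR-4485-3p, whose hairpin (chr11:10508270-10508326) shares sequence with the mitochondrial 16S rRNA, was higher by 3.70 ± 0.63, and by 4.85 without lysate replicate 1. miR-451a was at least 44.6-fold, miR-10394-3p at least 55.9-fold and miR-3960 at least 34.8-fold higher. miR-103a-3p (-2.92 ± 0.35), miR-378a-3p (-1.54 ± 0.25), miR-324-3p (-2.94 ± 0.70) and let-7b-5p (-1.41 ± 0.33) were lower, as was miR-4454 (-3.59 ± 0.57), whose sequence is close to a tRNA.

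The comparison gave 38 higher and 47 lower miRNAs. Of these 85, 77 did not overlap and 83 had the same sign in all 3 batch numbers. With library size only there were 42 and 42 (median moved by 0.12), in a fit of only these groups 33 and 29, and at equal depth 24 and 19. The list of entries overlapping other RNA classes had 11 higher and 2 lower (12 and 2 adjusted over the list alone; camera adjusted p = 8.17e-05, adjusted p = 0.220 with an estimated correlation). No other list passed, but 2 did without lysate replicate 1 and 3 without P100 replicate 4. Intestinal epithelial miRNAs had 0 higher and 6 lower (0 and 8 adjusted over the list alone), let-7 miRNAs 0 and 4, miR-17~92 miRNAs 0 and 3 (0 and 2 adjusted over the list alone) and vesicle associated miRNAs 5 and 0. Neural miRNAs had a median of -0.50 and a mean of 0.21 with a downward test.

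S100 against cell lysate asks which miRNAs had a larger or smaller share in the medium left after both spins than in the cells. Protein-bound RNA and the smallest particles remain in that medium. S100 RNA was precipitated before Trizol and lysate RNA was not, so an effect of preparation cannot be told apart. miR-22-3p was higher by 3.32 ± 0.35 (114782 ± 22197 CPM, n = 3, against 11507 ± 1527, n = 3). Higher too were miR-320a-3p (2.09 ± 0.39), miR-378a-3p (1.69 ± 0.28), the hypoxia-induced miR-210-3p (in MIR210HG, chr11:568089-568198; 2.87 ± 0.58) and miR-221-3p (1.97 ± 0.37), which targets cell-cycle inhibitors. miR-423-5p was higher by 3.09 ± 0.51, and by 3.84 without lysate replicate 1. miR-103a-3p (-4.71 ± 0.43) and miR-200c-3p (-3.70 ± 0.29; 3679 ± 374 CPM against 47722 ± 1906) were lower. miR-92a-3p was lower by a log2 fold change of -2.03 ± 0.30, and of -1.44 without lysate replicate 1. miR-10395-3p was at least 274-fold lower, with no count in S100.

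The call counts were 73 higher and 68 lower. Of these 141, 134 did not overlap and 138 had the same sign in both batch numbers that the 2 groups shared. The 6 fits without 1 library gave 79 to 89 higher and 51 to 57 lower, so none gave so even a split. Without the low-count filter the scaling changed, and 131 were higher and 58 lower with the median of all miRNAs moved by 0.69, while equal depth gave 42 and 36. Leaving out the filter moved that median by 0.65 against P40 and P100 and by 0.45 against total exRNA, so S100 fold changes shared an uncertainty of that size. No list passed (lowest camera adjusted p = 0.388). Vesicle associated miRNAs had 8 higher and 3 lower, and entries overlapping other RNA classes 6 and 7, with a median of -0.32, a mean of 0.21 and a downward test. Intestinal epithelial miRNAs had 3 and 8 (4 and 8 adjusted over the list alone), let-7 miRNAs 0 and 5, and miRNAs of the miR-10, miR-99, miR-100 and miR-125 family 2 and 3, with a median of -0.54, a mean of 0.29 and a downward test.

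Some miRNAs were called in the same direction in all 4 extracellular groups against lysate: 16 higher and 9 lower. The higher ones included miR-451a, miR-1246 and miR-10396b-5p, and the lower ones let-7a-5p, miR-103a-3p, miR-200c-3p and miR-194-3p. Simulated data without differences gave 0 in each of 50 draws, and independent lists of these sizes would share 0.316 and 0.303. The simulation held no change in any group, and the second value ignores the shared lysate. Neither therefore shows how many calls 4 comparisons with real changes would share through the lysate. Leaving out 1 lysate library gave 14 to 17 higher and 6 to 9 lower. The 4 comparisons use the same lysate libraries, which could not be split into parts of at least 2, so the part of the overlap due to them was not measured.

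**Figure D2:**
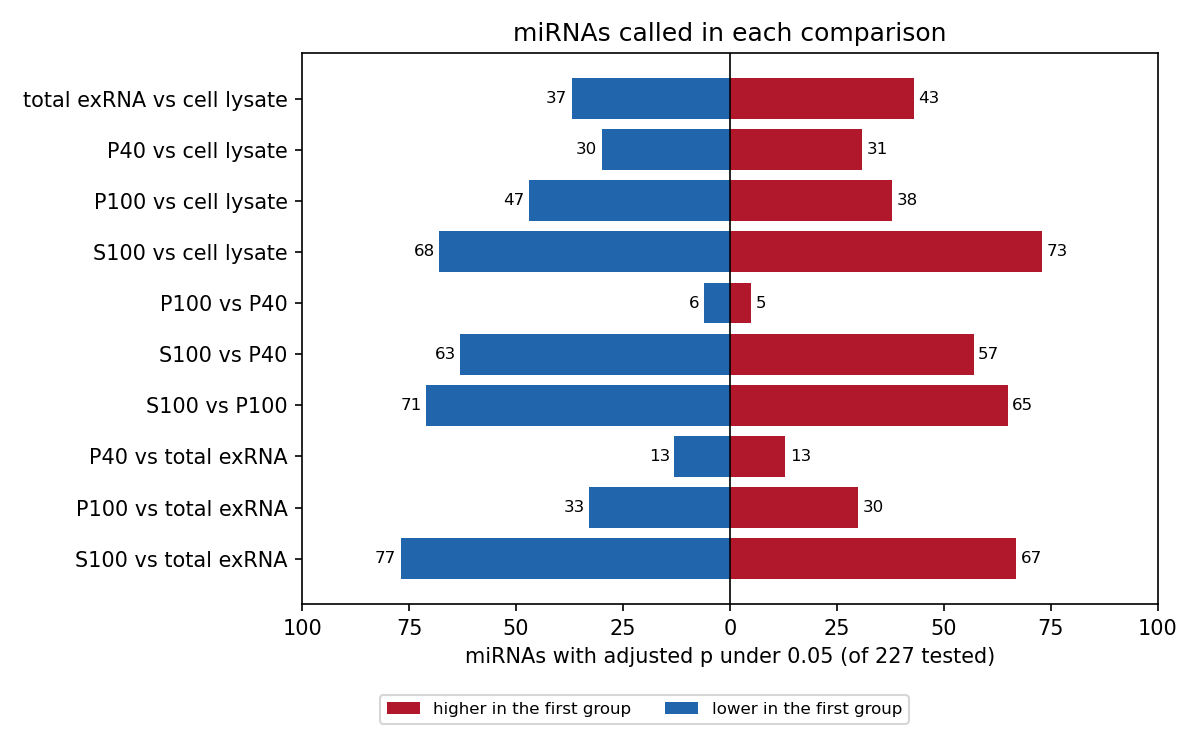
Numbers of miRNAs higher (right) and lower (left) in the first-named group of each comparison, at a Benjamini-Hochberg adjusted p below 0.05 in edgeR.

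P100 against P40 asks whether the 2 pellets differed. Few miRNAs were called, which does not show that few differed. In simulated data this comparison recovered 18% of changes of 2-fold and 66% of 4-fold. P40 libraries correlated with each other at a mean of 0.818, close to the 0.813 of P40 with P100. miR-10396a-3p (chr21:8987617-8987665) was higher in P100 by 3.57 ± 0.52 (5259 ± 1913 CPM, n = 4, against 433 ± 83.7, n = 4; edgeR adjusted p = 0.000107), and its near-identical neighbour miR-10396b-3p by 3.09 ± 0.56. miR-106a-5p, an X-linked relative of miR-17-5p that promotes growth, was lower by a log2 fold change of -4.17 ± 0.74, and of -4.89 without P100 replicate 2. miR-21-5p was lower, whereas miR-92a-3p (0.48 ± 0.25), miR-373-3p (-0.34 ± 0.27) and miR-200c-3p (0.23 ± 0.23) did not pass the test.

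In all, 5 miRNAs were higher and 6 lower. The other higher ones were miR-10396a-5p, miR-3960 and miR-3648 (the last chosen after its values were seen), and the other lower ones were miR-362-5p, miR-454-3p, miR-21-5p, miR-205-5p and miR-371a-5p. The number higher was 2 without P100 replicate 3, P100 replicate 4 or P40 replicate 2 and 3 without P100 replicate 1. The number lower was 1 without P100 replicate 3 or P40 replicate 2, 2 without P100 replicate 1 or 4 and 3 without P100 replicate 2. Of the 11 calls, 10 did not overlap and all 11 had the same sign in the 4 batch numbers. Library size only gave 5 and 16 (median moved by -0.22), DESeq2 10 and 7, a fit of only these groups 7 and 2, equal depth 6 and 4, and leaving out the 3 libraries set apart 8 and 12. The entries that overlap other RNA classes passed upward, with 2 higher and 0 lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.0113, adjusted p = 0.919 with an estimated correlation), but not without P40 replicate 3 or P40 replicate 4, or in a fit of only these groups. These were the libraries with the lowest share of that list in P40, 3.83% and 3.16% against 6.11% and 5.97%.

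S100 against P40 asks what separated the final supernatant from the first pellet. RNA preparation differed as well, since only S100 RNA was precipitated before Trizol. miR-22-3p (2.86 ± 0.31; 114782 ± 22197 CPM, n = 3, against 15811 ± 5329, n = 4), miR-378a-3p (2.61 ± 0.26), miR-483-5p (1.79 ± 0.28) and miR-221-3p (1.75 ± 0.33) were higher in S100. miR-301a-3p (in SKA2, chr17:59151136-59151221), which activates NF-kB signalling, was higher by 4.91 ± 0.52, and miR-338-3p by 4.02 ± 0.74. miR-1228-5p (LRP1, chr12:57194504-57194576) had no count in P40 and was at least 16.1-fold higher. miR-7704 (-5.40 ± 0.61), miR-194-3p (-4.16 ± 0.48) and miR-200c-3p (-2.52 ± 0.27) were lower. let-7b-5p was higher (1.73 ± 0.32) while its family member let-7a-5p was lower (-2.31 ± 0.44, and -1.55 without P40 replicate 3).

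There were 57 miRNAs higher and 63 lower, with 112 of 120 not overlapping and 112 of the same sign in all 3 batch numbers. Without the low-count filter there were 101 and 53, at equal depth 35 higher, and with library size only the median of all miRNAs moved by -0.17. No list passed (lowest camera adjusted p = 0.145), and 1 did without P40 replicate 4 or S100 replicate 3. Colorectal tumour miRNAs had 4 higher and 3 lower, with a median of 0.09, a mean of -0.17 and an upward test. Vesicle associated miRNAs had 6 and 5, with a median of -0.58, a mean of -0.19 and an upward test. Entries overlapping other RNA classes had 1 and 7, blood cell miRNAs 1 and 2 and let-7 miRNAs 2 and 3 (2 and 4 adjusted over the list alone).

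S100 against P100 asks how the 2 products of the last spin differed in the shares of their miRNAs. Because S100 RNA was precipitated before Trizol and P100 RNA was not, differences may also come from the preparation. miR-378a-3p, which acts in energy metabolism, was higher in S100 by 3.24 ± 0.26 (54659 ± 6178 CPM, n = 3, against 5787 ± 534, n = 4; edgeR adjusted p = 2.78e-09). miR-22-3p (3.47 ± 0.31), miR-210-3p (4.32 ± 0.56), miR-301a-3p (4.40 ± 0.51), miR-423-5p (2.30 ± 0.45) and miR-21-5p (1.31 ± 0.34) were higher as well. miR-7704 was lower by a log2 fold change of -6.58 ± 0.64 (1641 ± 488 CPM against 157709 ± 39994). The erythrocyte miRNAs miR-486-5p (-5.73 ± 0.62; from ANK1) and miR-451a (-3.26 ± 0.65; chr17:28861369-28861440) were lower, as were miR-194-3p (-4.87 ± 0.48), miR-200c-3p (-2.75 ± 0.27) and miR-92a-3p (-1.61 ± 0.28). Among the named miRNAs miR-4485-3p had the largest fall, -9.38 ± 0.84, which was -8.73 without S100 replicate 2 and -10.16 without S100 replicate 4.

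Of 136 calls, 65 were higher and 71 lower, 131 did not overlap and 133 had the same sign in all 3 batch numbers. Without the low-count filter there were 100 and 55. Entries overlapping other RNA classes had 0 higher and 12 lower (camera adjusted p = 0.00341, adjusted p = 0.639 with an estimated correlation), among them miR-4485-3p, and no other list passed. At equal depth 41 miRNAs were higher and 45 lower, and this list did not pass. Intestinal epithelial miRNAs had 5 higher, such as miR-192-5p (1.58 ± 0.40), a marker of gut and liver epithelium, and 5 lower. let-7 miRNAs had 2 and 4, with let-7b-5p higher (2.02 ± 0.33) and let-7a-5p lower (-2.36 ± 0.44). In the colorectal tumour list 5 were higher and 5 lower. miR-17~92 miRNAs had 3 and 3, with a median of -0.09, a mean of 0.45 and a downward test. Vesicle associated miRNAs had 6 and 4, with a median of 0.17, a mean of -0.03 and an upward test.

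Smaller lists were mixed between S100 and P100. The miR-10, miR-99, miR-100 and miR-125 family had 1 higher and 3 lower (1 and 4 adjusted over the list alone), with miR-100-5p (in MIR100HG, chr11:122152229-122152308) higher by 2.77 ± 0.57 and miR-99b-5p lower (-2.61 ± 0.43). Neural miRNAs (5 of 9 tested) had 1 higher, miR-138-5p (3.63 ± 0.73), and 1 lower, with a median of -0.26, a mean of 0.43 and an upward test. Blood cell miRNAs (3 of 12 tested) had 0 higher and 2 lower. The liver miRNA miR-122-5p, the 1 of 3 tested, was not called in any comparison. The mesenchymal list had 1 of 14 tested, miR-214-3p, called lower here (-1.78 ± 0.71), a call lost when any S100 library or P100 replicate 2 or 3 was left out. None of 7 muscle and 16 placenta cluster miRNAs was abundant enough to be tested, with mean shares of counts of 0.00568% to 0.0311% and 0.00157% to 0.0176% over the groups.

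**Figure D3:**
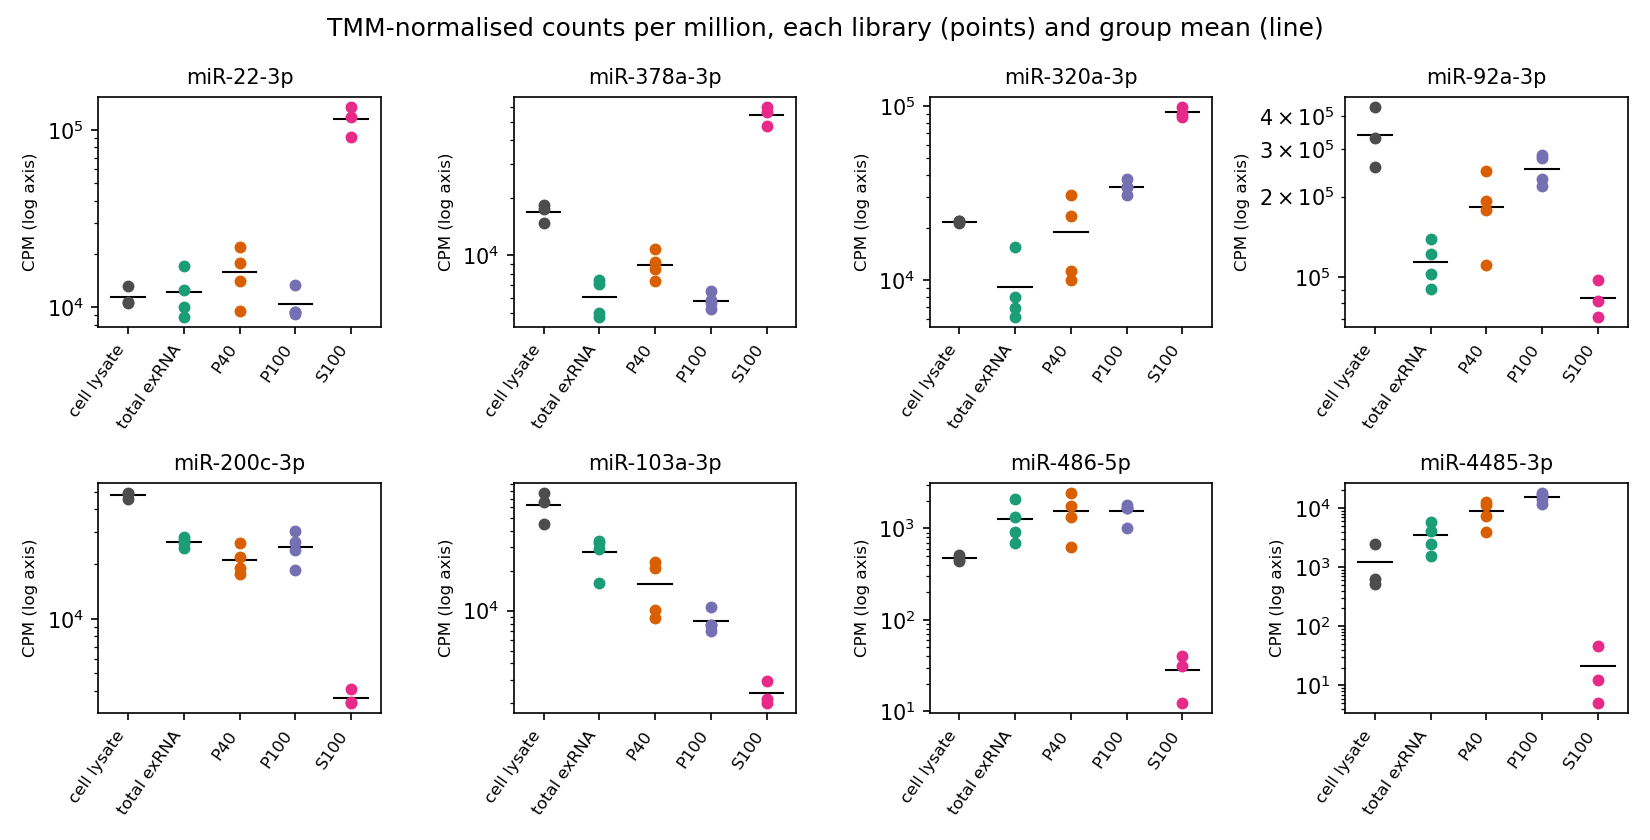
TMM-scaled CPM of 8 miRNAs in each library (points) with group means (lines), on a log scale.

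P40 against total exRNA asks how the first pellet differed from unfractionated medium. miR-1246 was higher in P40 by 2.26 ± 0.38 (7461 ± 3065 CPM, n = 4, against 1566 ± 206, n = 4), and miR-3651, encoded within the snoRNA SNORA84 (chr9:92292458-92292547), by 1.86 ± 0.34. miR-12136 (chr1:632615-632685) was higher by 3.21 ± 0.57, and by 4.09 without total exRNA replicate 2. miR-10396a-5p (-1.89 ± 0.36) and miR-4454 (-2.16 ± 0.52) were lower, as was miR-5100 (chr10:42997563-42997681; -4.38 ± 0.80, and -5.18 without P40 replicate 2).

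Calls numbered 13 higher and 13 lower, of which 18 of 26 did not overlap and 21 had the same sign in all 4 batch numbers. The number higher was 7 without total exRNA replicate 3 or 4, 8 without P40 replicate 3 or 4 and 25 without total exRNA replicate 2, and the number lower was 8 without P40 replicate 2. DESeq2 size factors gave 10 and 17, no filter 3 and 14, all libraries kept 9 and 15, a fit of only these groups 7 and 7, equal depth 11 and 8, DESeq2 17 and 23, and the set without the 3 libraries set apart 9 and 6. Vesicle associated miRNAs had 5 higher and 0 lower (6 and 0 adjusted over the list alone; camera adjusted p = 0.0309, adjusted p = 0.287 with an estimated correlation). This list alone passed, and none did at equal depth, in a fit of only these groups, without the 3 libraries set apart, or without P40 replicate 3, P40 replicate 4 or total exRNA replicate 3. With the replicate number as a block 2 lists passed, as without P40 replicate 1, and 3 passed without total exRNA replicate 2. The list moved with the libraries set apart, making up 9.66% and 10.3% of counts in P40 replicates 3 and 4 against 4.80% and 4.93% in replicates 1 and 2, and 6.37% in total exRNA replicate 2 against 3.60% to 4.57% in the others. Entries overlapping other RNA classes had 2 higher and 5 lower (4 and 7 adjusted over the list alone, camera adjusted p = 0.126). Colorectal tumour miRNAs had 0 and 2, with a median of 0.15, a mean of -0.08 and a downward test.

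P100 against total exRNA asks the same of the second pellet. miR-21-5p was lower in P100 by a log2 fold change of -2.32 ± 0.33 (11164 ± 3249 CPM, n = 4, against 55845 ± 14186, n = 4). miR-320a-3p (1.91 ± 0.33), miR-375-3p (1.84 ± 0.30), an enteroendocrine and islet miRNA and miR-483-5p (1.43 ± 0.27) were higher. Larger rises were those of miR-1180-3p (3.26 ± 0.56), miR-4508 (3.24 ± 0.86) and miR-10396a-3p (2.97 ± 0.48). miR-12136 was higher by 4.72 ± 0.58, and by 5.59 without total exRNA replicate 2. miR-30d-5p was lower (-1.12 ± 0.27).

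30 miRNAs were higher and 33 lower, with 53 of 63 not overlapping and 61 of the same sign in all 4 batch numbers. With library size only there were 26 and 41 (the median of all miRNAs moved by -0.18), at equal depth 23 and 19, and without the 3 libraries set apart 40 and 52. No list passed (lowest camera adjusted p = 0.0978). The miR-10, miR-99, miR-100 and miR-125 family had 3 higher and 0 lower (5 and 0 adjusted over the list alone), vesicle associated miRNAs 5 and 1 (6 and 2 adjusted over the list alone) and colorectal tumour miRNAs 1 and 4. Those overlapping other RNA classes had 4 and 4, with a median of -0.04, a mean of -0.07 and an upward test.

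S100 against total exRNA asks what the final supernatant held relative to unfractionated medium. miR-320a-3p (3.33 ± 0.36), miR-22-3p (3.24 ± 0.31), miR-423-5p (3.18 ± 0.46), miR-378a-3p (3.17 ± 0.26; 54659 ± 6178 CPM, n = 3, against 6054 ± 1375, n = 4) and miR-483-5p (2.88 ± 0.29) were higher. miR-7-5p, which restrains EGFR signalling, was higher by 4.91 ± 0.72, and miR-1228-5p was at least 41.6-fold higher. miR-30d-5p (-3.42 ± 0.32), miR-200c-3p (-2.85 ± 0.27), miR-7704 (-5.74 ± 0.62) and miR-4516 (in PKD1, chr16:2133119-2133204; -3.25 ± 0.71) were lower. miR-486-5p was lower by -5.42 ± 0.61, and by -4.79 without S100 replicate 3.

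The split was 67 higher and 77 lower, with 132 of 144 not overlapping and 138 of the same sign in all 3 batch numbers. Without the low-count filter there were 118 and 63, at equal depth 44 and 50, and with library size only the median of all miRNAs moved by -0.13. Entries overlapping other RNA classes had 1 higher and 11 lower (camera adjusted p = 0.0146, adjusted p = 0.897 with an estimated correlation), and no other list passed. None passed at equal depth. Total exRNA replicate 2 held a smaller share of this list (1.99%) than any S100 library (2.10% to 2.91%). Intestinal epithelial miRNAs had 3 and 8, and vesicle associated miRNAs 7 and 5. miR-17~92 miRNAs had 4 and 3 (3 and 2 adjusted over the list alone), with a median of -0.27, a mean of 0.15 and an upward test.

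Shares of counts of some lists rested on few members. Vesicle associated miRNAs made up 20.9% ± 2.05 of counts in S100 (SD, n = 3), 7.69% ± 0.58 in P100 (n = 4), 7.42% ± 2.97 in P40 (n = 4), 5.42% ± 0.464 in lysate (n = 3) and 4.68% ± 1.19 in total exRNA (n = 4). Most of the share in S100 came from miR-320a-3p (9.04%), miR-423-5p (5.90%) and miR-483-5p (4.33%). miR-17~92 miRNAs made up 38.2% ± 1.87 in lysate, 31.3% ± 1.87 in P100, 28.0% ± 4.65 in P40, 22.4% ± 0.718 in total exRNA and 14.9% ± 1.92 in S100, and most of this was miR-92a-3p (28.9% of lysate and 8.17% of S100 counts). Blood cell miRNAs were 0.358% ± 0.0519 of counts in P40, 0.257% ± 0.0589 in P100, 0.201% ± 0.0429 in total exRNA, 0.0722% ± 0.0146 in S100 and 0.0592% ± 0.00789 in lysate. These shares were not tested.

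**Figure D4:**
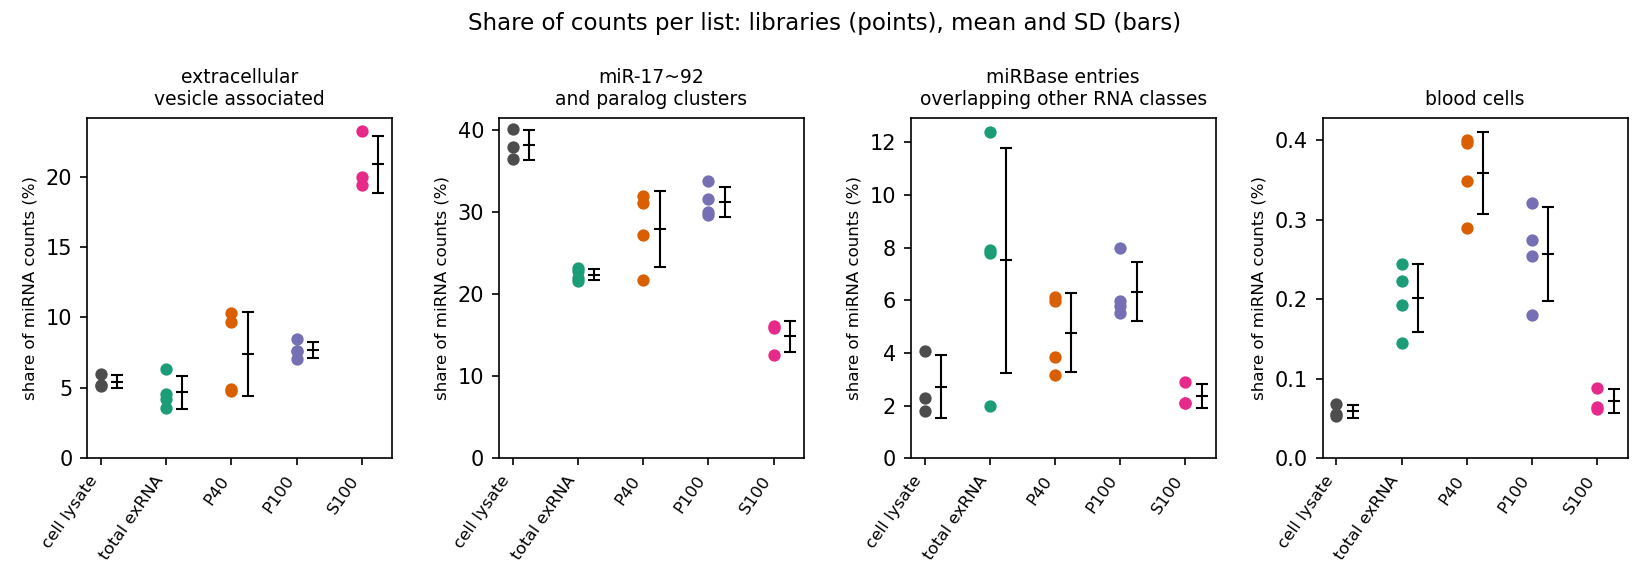
Share of counts of 4 miRNA lists in each library (points), with group means and SD.

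At an equal depth of 10017 counts, S100 libraries held 296 ± 0.603 detected miRNAs (SD, n = 3), total exRNA 285 ± 3.89, P40 280 ± 7.28, P100 266 ± 5.93 and lysate 256 ± 10.2. The order of the first 3 turned at 1001 counts (P40 136, S100 134, total exRNA 133) and with detection at 3 counts (P40 179, S100 175, total exRNA 171). Exact two-sided permutation tests of these numbers, of the share of the 10 most abundant miRNAs and of total counts could not reach an unadjusted p below 0.05 for groups with 3 libraries, the smallest possible p being 0.0571 with 3 and 4 libraries and 0.1 with 3 and 3. With 4 and 4 it was 0.0286, which P100 against total exRNA reached for detected miRNAs (Benjamini-Hochberg adjusted p = 0.0816) and for the share of the 10 most abundant (60.2% against 53.0%, adjusted p = 0.143). For detected miRNAs the adjusted p was 0.286 at 1001 counts and 0.381 with 3 counts. In the same exact permutation test P40 and P100 had lower total counts than total exRNA (p = 0.0286 each, adjusted p = 0.143). The share of the 10 most abundant lay between those of P100 and total exRNA in the other groups, while that of the single most abundant was highest in lysate (28.9%) and lowest in S100 (11.2%).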

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

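The tests of batch number and of exchanged labels below were chosen only after the result was seen, while the test of library depth was not.

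In 49 sets of 4 libraries, the gap between an extreme library and its nearest neighbour was compared with the whole range (Dixon's test at its 95% critical value). Chance singles out about 1 in 20 sets, and 3 were found. Total counts singled out S100 replicate 1, with a ratio of 0.882739. This library held 48 counts in a file the comparisons did not use, led by miR-378a-3p and miR-92a-3p with 6 counts each and miR-320a-3p with 4. Total exRNA replicate 2 stood out in the share of intestinal epithelial miRNAs (ratio 0.864371; 7.12% of counts against 5.86% to 6.03%) and of the miR-10, miR-99, miR-100 and miR-125 family (ratio 0.847524; 0.787% against 0.439% to 0.492%).

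Some miRNAs differed from lysate in opposite directions in 2 groups, with the direct comparison of those groups also passing edgeR's test. They were chosen after their values were seen. Between S100 and P40 there were 3 higher in S100 (miR-378a-3p, miR-296-5p and miR-23a-5p) and 3 lower (miR-4485-3p, miR-3651 and miR-486-5p). Between S100 and P100 there were 5 higher (miR-378a-3p, miR-130b-3p, miR-210-3p, miR-29c-3p and miR-17-3p) and 6 lower (miR-3651, miR-4485-3p, miR-7704, miR-486-5p, miR-12136 and miR-3195). miR-378a-3p, for instance, was at 1.69 in S100 and -1.54 in P100 relative to lysate, a direct difference of 3.24. P100 and total exRNA gave 1, miR-12136, at 2.89 in P100 and -1.83 in total exRNA. Between S100 and total exRNA there were 5 higher (miR-378a-3p, miR-483-5p, miR-320a-3p, miR-296-5p and miR-1180-3p) and 6 lower (miR-486-5p, miR-7704, miR-4485-3p, miR-16-5p, miR-3196 and miR-3195). The opposite signs relative to lysate rest on its 3 libraries.

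On the first component of deviations from group means (29% of that variance), total exRNA replicate 2 lay apart from its group (11.8). P40 split into pairs: replicates 3 and 4 (8.35 and 10.2) lay on the same side, and replicates 1 and 2 (-8.87 and -9.73) as far out on the other. The axis alone does not show which P40 pair is apart. The 3 libraries called set apart are P40 replicates 3 and 4 and total exRNA replicate 2, which lay together. In these 3 libraries the share of entries overlapping other RNA classes was lower, 3.83%, 3.16% and 1.99% of counts, against 5.97% to 12.4% in the other P40 and total exRNA libraries. Library depth was argued against, because at equal depth total exRNA replicate 2 still correlated with P40 replicates 3 and 4 at 0.55083 (0.488 at the deposited depth). Batch number stayed open: the 3 libraries bear different numbers, and their mean correlation of deviations with the lysate, P100 and S100 libraries of the same number was 0.00347725 (8 pairs, from -0.214 to 0.159), with a 95% interval of -0.0970 to 0.104 that leaves a small shared part possible. An exchange of labels between P40 and total exRNA could not be excluded. Exchanging total exRNA replicate 2 with P40 replicate 1 raised the calls between the groups from 26 to 47, yet P40 replicate 2 then correlated less with its own group than with the other (difference -0.0655). As labelled, that difference was -0.0240 for P40 replicate 1 and -0.00215 for P40 replicate 2. It was 0.0683 for P40 replicate 3, 0.0520 for P40 replicate 4 and 0.00863 for total exRNA replicate 2. Total counts followed the labels, with 61622 in total exRNA replicate 2 (34427 to 49164 in the others) and 14405 in P40 replicate 1 (10490 to 26096), but depth can also be set when libraries are pooled. A cause in the cultures or the isolation was not tested, since no label records one.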

How the results depend on the processing

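Over settings other than leaving out a library, 4646 values of the 518 named results were the same in call, 190 were weaker and 86 stronger. Counts that changed by more than 1.5-fold, and lists whose number changed, are given by setting, with the value of the report first.

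With library size only, miRNAs lower in total exRNA than in lysate went from 37 to 19, those of P40 against lysate from 31 and 30 to 47 higher and 19 lower with 2 lists, and those lower in P100 than in P40 from 6 to 16. With no filter, 21 were lower in total exRNA than in lysate and lists numbered 2 there, 6 for P40 and 5 for P100. S100 then had 131 higher than lysate, 101 than P40 with 1 list, 100 than P100 and 118 than total exRNA. P40 had 3 higher than total exRNA with 3 lists, and P100 against total exRNA had 3 lists. DESeq2 size factors gave 2 lists for P40 against total exRNA. DESeq2 gave 10 higher in P100 than in P40 and 23 lower in P40 than in total exRNA. With the replicate number as a block, lists numbered 4 for P40 against lysate and 2 for P40 against total exRNA. With all libraries kept, lists numbered 2 in each of these. Fits of only the 2 groups gave 16 higher and 11 lower in P40 than in lysate, 29 lower in P100 than in lysate, 2 lower in P100 than in P40 with 0 lists, and 7 higher and 7 lower in P40 than in total exRNA with 0 lists.

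Thinned to equal depth, 23 miRNAs were higher in total exRNA than in lysate, 18 and 14 were higher and lower in P40, 24 and 19 in P100, and 42 and 36 in S100. S100 then had 35 higher than P40, 41 higher and 45 lower than P100 with 0 lists, and 44 and 50 against total exRNA with 0 lists. Against total exRNA, P40 had 8 lower with 0 lists and P100 had 19 lower. Without the 3 libraries set apart, P40 had 17 lower than lysate with 2 lists, P100 had 8 higher and 12 lower than P40 with 0 lists, and S100 against P40 had 1 list. P40 then had 6 lower than total exRNA with 0 lists, and P100 had 52 lower. Removal of entries overlapping other RNA classes and the 2-fold minimum changed no count by more than 1.5-fold.

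Leaving out 1 library at a time gave 32 to 39 higher and 23 to 41 lower for total exRNA against lysate (1 to 2 lists), 23 to 35 and 22 to 33 for P40 (1 to 5), 33 to 40 and 32 to 42 for P100 (1 to 3) and 79 to 89 and 51 to 57 for S100 (0). It gave 2 to 6 and 1 to 6 for P100 against P40 (0 to 1 lists), 52 to 68 and 44 to 64 for S100 against P40 (0 to 1) and 60 to 67 and 53 to 68 for S100 against P100 (1). Against total exRNA it gave 7 to 25 and 8 to 17 for P40 (0 to 3), 24 to 40 and 24 to 36 for P100 (0) and 60 to 74 and 54 to 71 for S100 (1). Of values of named miRNAs, 209 were weaker, 42 stronger and 1 reversed: miR-4516 in S100 against lysate, -0.28 with all libraries, ranged from -0.40 to 1.75, the latter without lysate replicate 1, where it passed the test as higher.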

Other observations

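The tests of lysate depth, of serum and of linked miRNAs outside the list below, and all splits of the samples, were chosen only after the result was seen, while those of RNA fragments, S100 depth, hairpin GC and the make-up of total exRNA were not.

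The entries overlapping other RNA classes were lower in S100 than in P100, 12 of 16 tested, against 0 higher. Deeper sequencing of S100 was argued against, because at equal depth the median of the 11 members tested was -2.67726 (7 lower, 1 higher, upper quartile -1.67), although the list no longer passed there. High GC of the hairpins was argued against only in part. Among other miRNAs, the 50 of 200 with the highest GC differed from the rest by 0.163358 (two-sided permutation p = 0.734, bootstrap 95% interval -0.82 to 0.91). Those 50 began at 57.9% GC, whereas list members had a median of 73.5%, so an effect at the GC of the list stayed open. Fragments of rRNA, snoRNA and similar RNA counted as miRNAs stayed open. The 8 miRNAs linked to such RNA by locus or sequence differed from the rest by -2.87898 in their medians, but 5 of them belonged to the list, so the difference in large part restates the pattern. The 3 linked miRNAs outside it (-4.79, -2.38 and 0.85) were too few to decide (difference from other miRNAs -2.59, two-sided permutation p = 0.113). Of these, miR-10396b-3p and miR-10396b-5p (-4.79 and -2.38) are arms of the same hairpin but were counted separately in that test. The remaining one, miR-15a-5p, was linked only through a transcript annotated as misc_RNA and not as rRNA or snoRNA. The 11 list members without a link had a median of -2.59 with 9 lower, but the reference used held no 45S transcript sequence to compare them with. Nuclear tRNA was likewise compared by position only and not by sequence, so a missing link does not exclude a match to tRNA. S100 RNA was precipitated before Trizol and P100 RNA was not, which cannot be told apart from the fraction in this comparison. Against total exRNA, which was also precipitated, S100 had 11 members lower and 1 higher. Replicate 2 of total exRNA, however, held a smaller share of the list than any S100 library. Pelleting of ribosome-bound or vesicle-enclosed fragments, a biological reading, was not tested.

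miR-451a, made in erythroid cells, had 0 counts in lysate and 38 to 71 in each extracellular group. The depth of the lysate libraries was argued against, since 264.104 counts would be expected there at the share seen in P40. Carry-over of serum RNA into the medium may explain it, and stays open: the 3 other blood cell and liver miRNAs tested, miR-486-5p (1.70), miR-126-3p (0.16) and miR-122-5p (0.73), had a median of 0.7329 in P40 against lysate, too few to decide. Only miR-486-5p was called, and not at equal depth or without lysate replicate 2. Per the labels, the cells had 20% serum before the 24 h without it. Among blood cell miRNAs too rare to test, chosen after their values were seen, miR-150-5p had 1 count in lysate, 26 in P40, 12 in P100, 8 in total exRNA and 0 in S100. miR-223-3p, miR-142-3p and miR-144-3p had 0 to 2 counts in P40 and 0 or 1 in lysate. Selective release by the cells, the biological alternative, was not tested.

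Exact counts of other splits of the same libraries were made for each comparison. In 8 comparisons the real split alone gave the most calls, a share of 0.0286 (1 of 35 splits, the smallest possible). They were total exRNA against lysate (80 calls, highest other 46), P40 against lysate (61, 24), P100 against lysate (85, 30), P100 against P40 (11, 2), S100 against P40 (120, 82), S100 against P100 (136, 75), P100 against total exRNA (63, 15) and S100 against total exRNA (144, 99). Among the 8 splits that parted as many batch-number pairs, the highest other counts were 4, 17, 10, 0, 57, 51, 0 and 57 in that order, and 8 splits alone would be too few for a share below 0.05. Chance was therefore argued against only if the batch numbers mark no real pairs. For S100 against lysate (141, highest other 0) 10 splits were too few. Chance could not be excluded for P40 against total exRNA, where 3 of 35 splits gave at least as many as the real 26 and the highest gave 47 (32 among those parting as many pairs). That highest split joined P40 replicates 2, 3 and 4 with total exRNA replicate 2, which points to a structure of the samples other than the groups. For total exRNA against lysate the highest other split placed total exRNA replicate 2 with the lysate libraries.

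Total exRNA was taken from the medium that also gave P40, P100 and S100, so a mixture of the 3 could not lie outside their range. With library size only, 14 miRNAs were called on the same side of all 3: 7 higher (miR-1260b, miR-141-3p, miR-21-5p, miR-3196, miR-4454, miR-5100 and miR-663b) and 7 lower (miR-100-5p, miR-1180-3p, miR-1246, miR-320a-3p, miR-320b, miR-483-3p and miR-483-5p). TMM scaling gave 8 and 7. Simulated data with no difference between groups gave 0 in 50 draws, but mixtures of the 3 fractions were not simulated. The 7 higher made up 8.72% of total exRNA counts and the 7 lower 1.90%. The 14 calls argued against a plain mixture of the 3 as recovered, but with limits. Each had to be called between P40 and total exRNA, where chance could not be excluded, and no fit left out total exRNA replicate 2. With library size only, some varied widely in total exRNA, such as miR-3196 (4544 ± 3299 CPM, SD) and miR-663b (3390 ± 2790). Others did not, such as miR-141-3p (4077 ± 256). Total exRNA and S100 were precipitated and the pellets were not, which separates the pellets but not S100 from total exRNA.

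Chosen after their values were seen, the 2 strands of miR-371a differed: miR-371a-5p had 23392 CPM in lysate, 15662 in P40, 14663 in total exRNA, 8241 in P100 and 3536 in S100, whereas miR-371a-3p from the same hairpin stayed between 11101 and 15767 CPM in the 5 groups. In the neighbouring miR-373 the 5p strand went the other way, from 130 CPM in lysate to 307 in S100 (miR-373-3p, 58583 and 34598).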
